A study of Mus musculus with 9 samples.

How the data were processed

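Total RNA from 9 mouse samples was sequenced on an Illumina HiSeq, per the labels: 3 libraries each of CD133+, Nestin+ and CD133+Nestin+ progenitors of the third ventricular zone, sorted from mice with a Nestin promoter reporter. Groups were taken from the labels' cell population. Each label also carries a sort number, equal to a passage number, which served as the replicate number. Nothing in the labels says that libraries came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

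The submitters' processing notes name bcl2fastq, STAR 2.5.3a, Partek 8.0, limma and the mm10 build, with no role or order. How reads were assigned to genes, with which annotation and whether strand was used is not given in the sources used here, so overlapping and antisense genes and near-identical copies stay uncertain. The deposited table held normalized values for 18329 genes in 9 libraries. Their unit is not stated and was inferred from the values as CPM made by the authors with an offset of 0.0001: low values lay on steps of 0.0285 to 0.0344 CPM per read. Between 53.4% and 59.9% of low values were whole multiples of the step within a tolerance of 0.02 reads, so whole reads were not recovered and no count test was run. The listed genes summed to 65.9% to 87.6% of the CPM total, so the denominator included reads outside them. A level of 3 reads corresponded to 0.086 to 0.103 CPM, which covers counting error only. Few genes (37) had 0 reads in any library, so genes without reads in some library were mostly absent from the table, and 24 rows had symbols altered into dates, which were kept as given and not named. The authors' second deposited table gave a p-value, a step-up false discovery rate and a ratio of group means per gene for each pair of groups, per the file headers, and was used only as their result.

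Values were transformed as log2(CPM + 1), and genes at 1 CPM or more in at least 3 libraries were kept, which left 16143 genes and removed 2186. The 3 group means were fitted together in limma 3.58.1 under R 4.3.3, with trended and robust empirical Bayes variances (6 residual degrees of freedom, median prior 4.93). Each pairwise comparison and an F test over the 3 groups were adjusted by the Benjamini-Hochberg method at 0.05. Gene lists (31, of which 30 had at least 5 measured members) were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons together, and again with an estimated correlation and with fry. With the preset correlation 19, 14 and 10 lists were called in Nestin+ versus CD133+, CD133+Nestin+ versus CD133+ and CD133+Nestin+ versus Nestin+, and 0 of these held with an estimated correlation. In no called list did the median, the mean and the test differ in sign. Positions are from GENCODE M21 on GRCm38, the same build as mm10, in which 18219 symbols were found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

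The replicate numbers were checked for pairing. Deviations from the group means correlated at 0.204 to 0.73 across genes in the 9 pairs of libraries with the same number and at -0.527 to 0.314 in pairs with different numbers, and 8 of the 9 libraries correlated best with their own number in both other groups. The numbers were therefore taken to pair the samples, from the data and not from a statement in the labels, and the fit with the number as a block is given where it moves a gene count or a printed member count of a list by over 1.5 times. The main fit, fixed beforehand, has no block and leaves the effect of the number in the error. Unless the block is named, printed SEs, adjusted p-values, calls and fits that left out 1 library are without it.

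The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Prom1 and Nes were always named. In each comparison the 8 genes with the largest rises and the 8 with the largest falls were eligible, among those past the threshold with groups that did not overlap, a mean of at least 10 CPM in the higher group and no symbol of a predicted gene. Up to 4 members of smallest p were eligible from each list with a called member. Some results for single genes are not reported here. Alternatives were the replicate block, a pseudocount of 0.1, no filter, a filter of 5 CPM, median centring, quantile normalization, library weights, the 6 libraries compared alone, no trend or robust prior, and leaving out each library. The fits with the libraries numbered 2 and 3 only, and with the block but without CD133+Nestin+ replicate 2, were added after seeing the data.

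The procedure was tested on simulated data with the real means and residual spreads and independent normal noise, with 200 of 16143 genes changed, drawn from those above 10 CPM. For Nestin+ versus CD133+, 65% of genes changed by a log2 of 2 and 4% of those changed by 1 were recovered. The shares were 63% and 10% for CD133+Nestin+ versus CD133+, and 68% and 8% for CD133+Nestin+ versus Nestin+. Calls among unchanged genes numbered 3 of 72, 6 of 79 and 4 of 80 calls in the same order. The simulated noise lacked the correlation between genes and the pairing by number seen in these data. These shares therefore do not give the error rate of the real calls.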

Results

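RNA sequencing was performed on neuroglial progenitors of the third ventricular zone (TVZ), the germinal tissue that lines the third ventricle of the brain, from mice harvested on postnatal day 1. The mice carried a reporter in which the Nestin promoter drives a nuclear cyan fluorescent protein (CFP). Cells were separated by flow cytometry on CFP and on CD133, the surface protein encoded by Prom1, into 3 populations with 3 libraries each: CD133+, Nestin+ and CD133+Nestin+. The labels do not state whether the cells sorted on a single marker lacked the other marker. The study's design text concerns functional and molecular differences between such isolated progenitors, and the 3 pairwise comparisons address the molecular part. Deposited values were taken as CPM (reads scaled to the library total), a unit inferred from the values, in which 1 read corresponded to 0.0285 to 0.0344 CPM. Levels are given as mean CPM ± SD with n = 3 libraries per group, and fold changes as log2 ± SE on the log2(CPM + 1) scale, which understates the change of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 16143 genes.

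The transcripts of both sort markers followed the labels. Prom1 (chromosome 5, 43993620 to 44102032, GRCm38) stood at 169 ± 20 CPM in CD133+, 147 ± 32.7 in CD133+Nestin+ and 51 ± 10.3 in Nestin+ libraries. Nes (chromosome 3, 87971078 to 87980451) stood at 51.2 ± 10.1 CPM in CD133+, 173 ± 20 in Nestin+ and 198 ± 22.6 in CD133+Nestin+ libraries. An exact two-sided permutation test gave p = 0.1 for Prom1 between Nestin+ and CD133+, the smallest that 3 libraries against 3 allow, and p = 0.3 between CD133+Nestin+ and CD133+. For Nes the exact permutation test gave p = 0.1 between CD133+ and either other group, and p = 0.2 between CD133+Nestin+ and Nestin+. The permutation test takes the libraries as exchangeable and leaves out the pairing by number. Because the cells were chosen by these markers, the differences check the labels and are not findings.

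Along the first principal component, with 38.8% of the variance, the CD133+ libraries lay at one end, the Nestin+ libraries at the other and the CD133+Nestin+ libraries between them. The second component, with 32.5%, set CD133+Nestin+ replicate 2 apart at -108, while all other libraries lay between -19.3 and 57.1. That library correlated with the others at r = 0.802 to 0.896 across genes, which are not independent replicates. Over the 3 groups together, 1534 genes passed limma's F test, and 2656 did so with the replicate number as a block. The count fell to 862 without Nestin+ replicate 2 and to 984 without Nestin+ replicate 3.

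**Figure D1:**
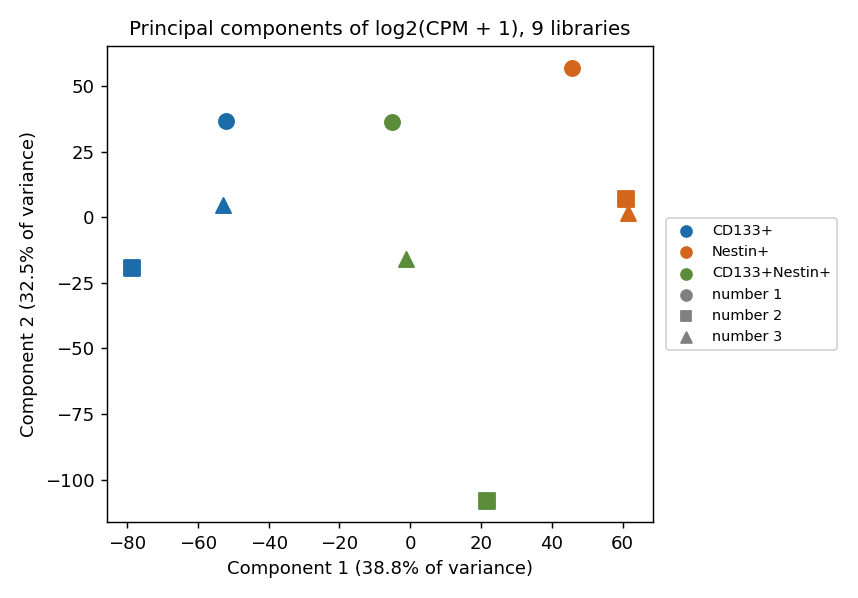
Each point is 1 of the 9 libraries, placed by its scores on the first (38.8% of variance, horizontal) and second (32.5%, vertical) principal components of log2(CPM + 1), with color for the group and shape for the replicate number. CD133+Nestin+ replicate 2 lies at -108 on the second component.

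Compared with CD133+ cells, Nestin+ cells had far lower levels of genes of ciliated ependymal cells, blood vessels, immune cells and red blood cells, and higher levels of genes of oligodendrocyte precursors. Of 19 measured genes of ependymal cells and motile cilia, 18 fell (19 adjusted over the list alone). Foxj1, the master regulator of motile ciliogenesis (chromosome 11, 116330704 to 116335399), stood at 31.9 ± 7.3 CPM in Nestin+ and 260 ± 139 in CD133+ libraries, a log2 change of -2.89 ± 0.35. Mcidas, which drives multiciliated cell fate, changed by -4.50 ± 0.35, and Rsph1, a radial spoke gene, by -3.28 ± 0.30. All 15 measured microglia and macrophage genes fell (15 adjusted over the list alone), among them C1qc at -4.56 ± 0.56 and Lyz2 at -5.29 ± 0.65. All 7 measured endothelial genes fell (7 adjusted over the list alone), led by Cldn5, a tight junction gene of brain vessels, at 0.408 ± 0.541 against 238 ± 72 CPM. Of 13 mural and fibroblast genes, 6 fell (7 adjusted over the list alone), including Dcn at -6.45 ± 0.43 and Col1a1 at -5.03 ± 0.47. With camera's preset correlation the adjusted p was 8.96e-18 for the ependymal, 2.64e-15 for the microglial, 1.2e-11 for the endothelial and 7.95e-06 for the mural list. With an estimated correlation none of these calls held, at an adjusted p = 0.206 for the microglial list and an adjusted p = 0.195 for the other lists of this group. Fry called all of them, at an adjusted p of 0.00218 for the ependymal, 0.00809 for the microglial, 0.00139 for the endothelial and 0.0018 for the mural list.

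Oligodendrocyte precursor genes formed the highest list in Nestin+ cells, with 9 of 14 measured members higher (11 adjusted over the list alone) and a median log2 change of 2.5. Gpr17, a receptor of committed precursors, stood at 159 ± 66.6 CPM against 3.94 ± 1.55, and Pdgfra, the growth factor receptor of precursors (chromosome 5, 75152292 to 75198215), at 399 ± 138 against 25.3 ± 7.44. Sox10, the lineage's transcription factor, rose by 3.99 ± 0.47. Of 14 neuronal lineage genes, 6 rose (7 adjusted over the list alone), among them the migrating neuroblast gene Dcx at 2.91 ± 0.48 and the synaptic gene Snap25 at 2.5 ± 0.42. The neuronal count ranged from 3 to 8 when 1 library was left out. Camera's adjusted p was 4.77e-12 for the precursor and 5.93e-06 for the neuronal list, and each had an adjusted p = 0.195 with an estimated correlation. Fry's adjusted p was 0.0103 for the precursor and 0.0101 for the neuronal list. Outside the lists, Plppr1 (4.19 ± 0.38), Zdhhc22 (4.18 ± 0.44), the adhesion gene Cntn1 (4.17 ± 0.54) and St8sia3 (3.90 ± 0.73) were among the largest rises.

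Several signalling and regional lists moved with fewer called members. Among 14 genes induced by RAS and MAPK signalling, Etv1, Etv4, Etv5 and Spry4 rose and Ier3 fell (5 higher and 1 lower adjusted over the list alone), with Etv4 at 2.20 ± 0.45. The list's adjusted p was 0.00186, and the adjusted p = 0.385 with an estimated correlation. With only the libraries numbered 2 and 3, 2 of its members were higher, and Spry4 and Etv1 were not called. The call of Etv5 was lost without any of 4 single libraries and that of Ier3 without any of 5.

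In the list for the hypothalamus and tanycytes, the radial glia of the third ventricle, Col23a1 (2.49 ± 0.28), Crym (2.61 ± 0.33) and Rax were higher and Fezf1 was lower (8 and 1 adjusted over the list alone). Its adjusted p was 0.000159, and the adjusted p = 0.195 with an estimated correlation. Rax lost its call without any of 6 single libraries and Fezf1 without any of 5, while 5 members were higher with the replicate block and 6 without CD133+Nestin+ replicate 2. Hhip and Ptch1, of 10 hedgehog targets, rose by 1.72 ± 0.38 and 1.08 ± 0.29 (2 adjusted over the list alone), with a list adjusted p of 0.00742 and an adjusted p = 0.195 with an estimated correlation. Hhip lost its call without any of 3 single libraries, Ptch1 without any of 5 and both with only the libraries numbered 2 and 3, whereas the block gave 4 members. The list of 20 cholesterol synthesis genes had a median of 0.85 and an adjusted p of 1.08e-05, and the adjusted p = 0.44 with an estimated correlation.

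Genes of inflammation and of blood were lower in Nestin+ than in CD133+ cells. Microglial and endothelial genes fell in the same comparison, and whether cells of those types account for the inflammation genes was not tested. Of 16 interferon response genes 6 fell (12 adjusted over the list alone), with Oasl2 at -3.15 ± 0.41 and Bst2 at -3.12 ± 0.44. Antigen presentation genes fell in 4 of 10 cases (5 adjusted over the list alone), including H2-T23 at -1.86 ± 0.32, and chemokine genes in 3 of 5 (3 lower and 1 higher adjusted over the list alone), with Ccl12 at -4.43 ± 0.35. The adjusted p of these lists was 1.24e-06, 0.00245 and 0.00488. These calls were lost with an estimated correlation, at an adjusted p = 0.195, an adjusted p = 0.321 and an adjusted p = 0.271 in the same order. The interferon count was 10 and 11 without CD133+Nestin+ replicate 1 and 2, and the antigen presentation count ranged from 1 to 5 when 1 library was left out. All 5 measured erythroid genes fell (5 adjusted over the list alone), at a list adjusted p of 0.000147 and an adjusted p = 0.288 with an estimated correlation. The alpha globin genes Hba-a1 and Hba-a2 are near-identical copies whose reads could be divided between them, and with only the libraries numbered 2 and 3, 1 erythroid gene remained called. When 1 library was left out 3 to 5 were called, and Alas2 lost its call without any of 4 single libraries. Of 16 immediate early genes 4 fell (4 adjusted over the list alone), at an adjusted p of 0.0198 and an adjusted p = 0.727 with an estimated correlation. That list lost its call without CD133+ replicate 3 or Nestin+ replicate 1, and its called members ranged from 0 to 4 when 1 library was left out and were 7 with the block.

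The neural stem, astrocyte, neuronal commitment and Notch lists passed with the preset correlation, with medians of 0.53 to 0.66 (log2) and few called members. Of 16 neural stem and radial glia genes, Hes5 (3.01 ± 0.81) and Ptprz1 (1.77 ± 0.51) were higher and Pax6 (-1.50 ± 0.38) was lower (2 and 1 adjusted over the list alone). Hes5 lost its call without any of 4 single libraries, Ptprz1 without any of 5 and Pax6 without any of 3, and with the replicate block 5 members were higher and 1 lower. The list's adjusted p was 0.00333, and the adjusted p = 0.51 with an estimated correlation. Without CD133+ replicate 2 the list was no longer called, at an adjusted p of 0.0528. Astrocyte genes (2 of 18 higher, 2 adjusted over the list alone), neuronal commitment factors (2 of 9, 2) and Notch genes (2 higher and 2 lower of 14, 3 and 2) passed at an adjusted p of 0.0301, 0.0053 and 0.0456. They had an adjusted p = 0.727, an adjusted p = 0.336 and an adjusted p = 0.554 with an estimated correlation. Fry did not call the neural stem, astrocyte, commitment, Notch, RAS and MAPK, cholesterol or immediate early lists. Its adjusted p was lowest among these for the commitment list, at 0.0809. The astrocyte list was lost without CD133+ replicate 2 or Nestin+ replicate 1, and the Notch list without any of 5 single libraries. With the block 6 astrocyte genes were higher and 1 lower, and leaving out 1 library gave 0 to 2 called commitment factors and 0 to 3 higher Notch genes.

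The lists for DNA replication (0 of 19 members called), mitosis (2 of 20 lower), myelin (1 higher and 2 lower of 7), telencephalic factors (2 and 1 of 7), Schwann and neural crest cells (1 and 2 of 7), BMP targets (1 of 10 lower), WNT targets (4 of 9 lower), hypoxia and glycolysis (4 of 20 lower), unfolded protein response (0 of 16), p53 targets (1 of 13 lower) and extracellular matrix (4 and 8 of 21) did not pass as lists. Leaving out 1 library gave 1 to 5 lower mitosis, 2 to 4 lower WNT and 1 to 4 lower hypoxia genes, 1 to 4 higher and 5 to 9 lower matrix genes, and 0 to 2 higher telencephalic and myelin genes. It gave 0 to 2 lower BMP targets and unfolded protein genes. The replication list was called in 4 of the 9 fits that left out 1 library and the mitosis list in 2. With the block the lists in this group still did not pass, and 1 replication gene was higher, 4 mitosis genes were lower, 7 matrix genes were higher and 2 p53 targets were lower. BMP targets then had 2 higher and 2 lower, Schwann and neural crest genes 2 higher, telencephalic factors 2 lower and the unfolded protein response 1 in each direction. The list calls in this paragraph are camera's. Fry called the WNT and matrix lists as lower, at an adjusted p of 0.00731 and 0.025. The Hox list had 2 measured members and was not tested.

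In total 1915 genes differed between Nestin+ and CD133+ cells, 395 higher and 1520 lower in Nestin+, and groups did not overlap for 33% of genes, where chance gives 10%. That 10%, here and in the other comparisons, takes the libraries as exchangeable, which the pairing by number goes against. With the replicate number as a block 3094 genes were called, 978 higher and 2116 lower, and all 1915 were among them. Another scaling changed the balance: median centring gave 587 higher and 1300 lower and quantile normalization 696 and 1370, and these moved the median of all genes by 0.135 and 0.147 (log2). The count fell to 1082 without CD133+ replicate 2 and to 1162 without Nestin+ replicate 2, and it was 4182 with library weights. Leaving out 1 library gave 152 to 729 higher and 930 to 2034 lower genes.

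**Figure D2:**
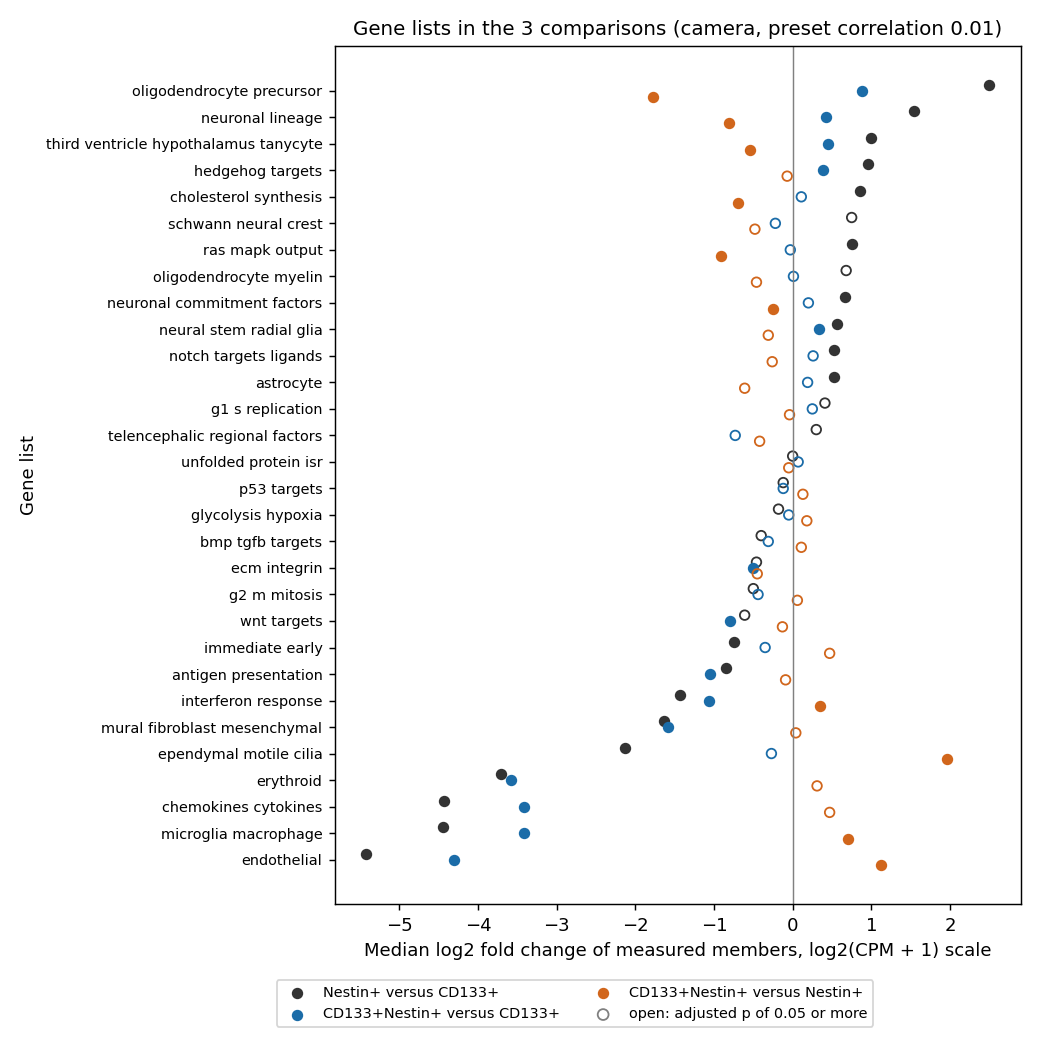
Each point is the median log2 fold change (horizontal axis, log2(CPM + 1) scale) of the measured members of 1 gene list (vertical axis) in 1 of the 3 comparisons, filled where camera's adjusted p with the preset correlation was under 0.05 and open elsewhere. The endothelial list lies at -5.42 in Nestin+ versus CD133+, and the ependymal list lies at -2.13 there and at 1.96 in CD133+Nestin+ versus Nestin+.

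CD133+Nestin+ cells had lower levels than CD133+ cells of listed genes of blood vessels, immune cells and connective tissue, whereas the ependymal list was not called with all libraries. Of 15 microglia and macrophage genes 14 fell (15 adjusted over the list alone), including Csf1r, the receptor that microglia need to survive, at 25 ± 29.6 against 342 ± 195 CPM. All 7 endothelial genes fell (7 adjusted over the list alone), with Pecam1 at -4.31 ± 0.40 and Flt1 at -3.07 ± 0.38. Of 13 mural and fibroblast genes 6 fell (9 lower and 1 higher adjusted over the list alone), with Col1a1 at -5.40 ± 0.47 and Fn1 at -3.18 ± 0.25. The adjusted p of these lists was 7.58e-20, 1.38e-15 and 9.03e-09, and each had an adjusted p = 0.195 with an estimated correlation. The endothelial count stayed at 7 whichever library was left out, whereas the microglial count fell to 5 and 2 without CD133+ replicate 1 and 3, and to 7 and 6 without CD133+Nestin+ replicate 2 and 3. Of 19 ependymal genes 1 fell, Mcidas at -1.75 ± 0.35 (1 adjusted over the list alone), and the list's median was -0.27 at an adjusted p of 0.287. Without CD133+ replicate 1 or 3 that list was called, and Mcidas lost its call without any of 4 single libraries.

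Extracellular matrix genes fell in 7 of 21 cases (10 lower and 2 higher adjusted over the list alone), including the basement membrane collagens Col4a1 (-1.92 ± 0.23) and Col4a2 (-2.40 ± 0.28), at a list adjusted p of 0.000608 and an adjusted p = 0.385 with an estimated correlation. Interferon (3 of 16 lower, 9 adjusted over the list alone), antigen presentation (3 of 10, 6), chemokine (3 of 5, 3), erythroid (4 of 5, 5) and WNT target (2 of 9, 4) genes passed as lists. Their adjusted p was 3.57e-06, 7.57e-05, 0.000239, 1.89e-06 and 0.0156 in that order. The interferon, chemokine and WNT lists had an adjusted p = 0.195 with an estimated correlation, and the antigen presentation and erythroid lists an adjusted p = 0.206 with an estimated correlation. Without any of the 3 CD133+ libraries, or without CD133+Nestin+ replicate 2, 0 erythroid genes were called, and without CD133+Nestin+ replicate 1 the WNT list had an adjusted p of 0.0902. When 1 library was left out, 0 to 4 interferon, 0 to 3 antigen presentation, 1 to 2 WNT and 4 to 7 matrix genes were lower, and with the block 5 antigen presentation genes were.

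A smaller set of genes was higher in CD133+Nestin+ than in CD133+ cells. The WNT ligand gene Wnt8b stood at 76.4 ± 43.4 against 10.7 ± 4.5 CPM, and the homeobox gene Dbx1, a regulator of progenitor domains, at 26.7 ± 11.5 against 4.71 ± 0.347. The phosphatase gene Ptpn5 rose by 2.47 ± 0.38, Pdzph1 by 2.41 ± 0.42, Plppr1 by 2.13 ± 0.38 and Pcolce2 by 2.07 ± 0.33. Without CD133+ replicate 3 Pdzph1, Plppr1 and Pcolce2 were not called, and Pdzph1 and Plppr1 were not called with only the 6 libraries compared. Pdzph1 also lost its call without CD133+Nestin+ replicate 3, and Plppr1 without CD133+ replicate 2. Of 14 oligodendrocyte precursor genes 1 was called, Gpr17 at 2.63 ± 0.59 (4 adjusted over the list alone), with a list adjusted p of 7.57e-05 and an adjusted p = 0.385 with an estimated correlation. Gpr17 stood at 38.8 ± 37.4 CPM in CD133+Nestin+ libraries, and its call was lost when any of 7 single libraries was left out, whereas 3 precursor genes were called with the replicate block. The neural stem, neuronal, tanycyte and hedgehog lists passed with 0 members called over all genes, at an adjusted p of 0.021, 0.00333, 0.0128 and 0.0104. With an estimated correlation they had an adjusted p = 0.653, an adjusted p = 0.27, an adjusted p = 0.288 and an adjusted p = 0.195. Of these fry called only the hedgehog list, at an adjusted p of 0.0447. Fry did not call the precursor list, at 0.305. Adjusted over the list alone, 1 neuronal gene was higher, and 2 tanycyte genes were higher and 1 lower. Without CD133+Nestin+ replicate 1 the precursor (adjusted p of 0.0679), neuronal (0.133), tanycyte (0.05) and neural stem lists were no longer called, and the last was also lost without CD133+ replicate 2. With the block 3 tanycyte genes were higher and 1 lower, and 1 neuronal gene was higher.

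Of the 390 genes called between CD133+Nestin+ and CD133+ cells, 48 were higher and 342 lower in CD133+Nestin+, and 17.5% of genes had groups that did not overlap, where chance gives 10%. With the replicate block 776 were called, 181 higher and 595 lower, all 390 among them. The count was 238, 214 and 131 without CD133+ replicate 1, 2 and 3, 236 without CD133+Nestin+ replicate 3, 198 with only the 6 libraries compared and 711 with library weights. The higher genes numbered 75 with median centring and 77 with quantile normalization, and 7 to 72 when 1 library was left out.

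CD133+Nestin+ and Nestin+ cells, which had like levels of Nes, were separated by the ependymal genes. Of 19 members 17 were higher in CD133+Nestin+ cells (19 adjusted over the list alone), among them Tmem212 at 196 ± 17.3 against 14 ± 2.67 CPM, Rsph1 at 236 ± 33.1 against 34.8 ± 4.03 and Mcidas at 33.2 ± 4.37 against 4.13 ± 1.25. The list's adjusted p was 1.8e-27, and the adjusted p = 0.195 with an estimated correlation. Fewer members were called without Nestin+ replicate 2 (10), Nestin+ replicate 3 (8) or CD133+Nestin+ replicate 3 (9). Outside the list, Ccdc153 (4.02 ± 0.50), Cdhr3 (4.45 ± 0.58), Tctex1d4 (4.05 ± 0.33), the cyclin gene Ccna1 (4.45 ± 0.63) and the serotonin receptor gene Htr5b (4.03 ± 0.39) were among the largest rises. The hypoxia-responsive carbonic anhydrase gene Car9 rose by 3.18 ± 0.41, and the cell cycle inhibitor gene Cdkn1a by 1.41 ± 0.30, a call lost without any of 5 single libraries. They were the only called members of the hypoxia and glycolysis list (1 of 20, 3 adjusted over the list alone) and of the p53 list (1 of 13, 1), which did not pass at an adjusted p of 0.141 and 0.349. With the replicate block 2 hypoxia and glycolysis genes were higher.

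Oligodendrocyte precursor genes were lower in CD133+Nestin+ than in Nestin+ cells, with 4 of 14 members called (9 adjusted over the list alone). Pdgfra stood at 73.6 ± 81.7 against 399 ± 138 CPM, Cspg4 at 40.7 ± 34.5 against 167 ± 30.1 and Sox10 at 6.12 ± 4.02 against 26.1 ± 3.72. The list's adjusted p was 2.92e-10, and the adjusted p = 0.206 with an estimated correlation. Without any of the 3 Nestin+ libraries, or without CD133+Nestin+ replicate 2 or 3, 0 members were called, and there were 6 with only the libraries numbered 2 and 3, and 7 with the replicate block or without CD133+Nestin+ replicate 1. Pdgfra, Sox10 and Cspg4 each lost their call without any of 6 single libraries. The tanycyte gene Col23a1 fell by 1.43 ± 0.28 on the log2 scale, the 1 member called of 11 (3 adjusted over the list alone), at a list adjusted p of 0.00245 and an adjusted p = 0.206 with an estimated correlation. Col23a1 lost its call without any of 3 single libraries, and with the block 2 members were called. The neuronal, RAS and MAPK, and cholesterol lists were lower with 0 members called over all genes (4, 1 and 0 adjusted over the list alone), at an adjusted p of 0.000768, 3.59e-05 and 4.24e-06. With an estimated correlation they had an adjusted p = 0.206, an adjusted p = 0.271 and an adjusted p = 0.421. With the block 3, 3 and 4 of their members were called lower.

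Few vascular and immune genes differed between these groups. Cldn5 was called at 8.26 ± 5.94 against 0.408 ± 0.541 CPM, the 1 endothelial member of 7 (3 adjusted over the list alone), and Dcn at 9.78 ± 5.13 against 0.28 ± 0.0967. The call of Cldn5 was lost without any of 5 single libraries, and leaving out 1 library gave 0 to 3 higher endothelial members. The endothelial, microglial and interferon lists were higher in CD133+Nestin+ cells at an adjusted p of 0.00333, 0.0104 and 0.0465, with 0 microglial (1 with the block) and 0 interferon members called. The same lists, with an estimated correlation, had an adjusted p = 0.359, an adjusted p = 0.727 and an adjusted p = 0.42. With the replicate block the interferon list was not called, at an adjusted p of 0.0616, and the astrocyte and immediate early lists were called, at 0.0104 and 0.00976. Those calls were lost in the blocked fit at an adjusted p = 0.351 and an adjusted p = 0.532 with an estimated correlation. Neuronal commitment factors were lower at an adjusted p of 0.0488, and the adjusted p = 0.49 with an estimated correlation, with 0 members called and 1 with the block. That list, the interferon list and the microglial list lost their calls without 5, 5 and 3 of the 9 single libraries.

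Of the 505 genes called between CD133+Nestin+ and Nestin+ cells, 464 were higher and 41 lower in CD133+Nestin+, and 17.3% of genes had groups that did not overlap, where chance gives 10%. With the replicate block 983 were called, 803 higher and 180 lower, all 505 among them. The count was 281, 172 and 226 without Nestin+ replicate 1, 2 and 3, and 180 without CD133+Nestin+ replicate 3. The lower genes numbered 1, 8 and 2 without Nestin+ replicate 2, Nestin+ replicate 3 and CD133+Nestin+ replicate 3, and 145 without CD133+Nestin+ replicate 1.

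**Figure D3:**
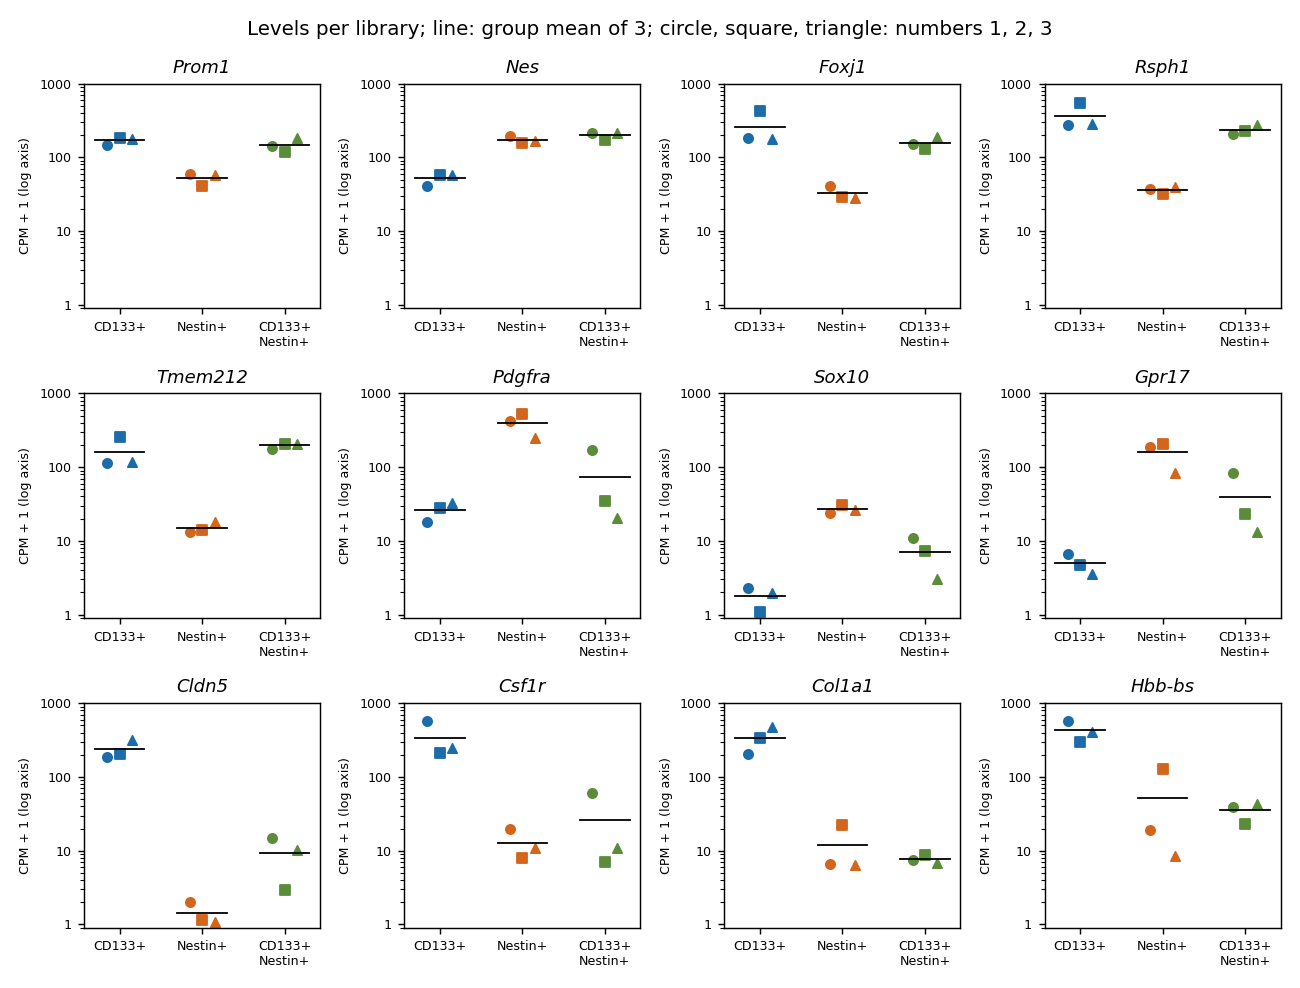
Each panel shows the level of 1 gene in the 9 libraries as CPM + 1 on a log axis, with symbols for the replicate numbers and a line at the mean of 3 libraries. Foxj1, Rsph1 and Tmem212 lie lowest in Nestin+, Pdgfra, Sox10 and Gpr17 highest in Nestin+, and Cldn5, Csf1r, Col1a1 and Hbb-bs highest in CD133+ libraries.

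The authors' deposited table held their own comparisons of the 3 groups over 18329 genes. At a step-up false discovery rate under 0.05, the authors' deposited table had 1662 genes for Nestin+ versus CD133+, 310 higher and 1352 lower in Nestin+, and 1620 of them were called in the same direction by the fit made here. For Nestin+ versus CD133+Nestin+ the authors' deposited table had 475 genes, of which 451 were called here in the same direction. For CD133+ versus CD133+Nestin+ the authors' deposited table had 175 genes, of which 174 were called here in the same direction. Both sets rest on the same libraries and are not independent.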

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

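The fits with libraries numbered 2 and 3 only, and with the replicate block but without CD133+Nestin+ replicate 2, were chosen after the data were seen. With the replicate block the counts were 3094 (Nestin+ versus CD133+), 776 (CD133+Nestin+ versus CD133+), 983 (CD133+Nestin+ versus Nestin+) and 2656 (any group), against 1915, 390, 505 and 1534. With the block and without CD133+Nestin+ replicate 2 they were 4916, 807, 1324 and 4127. Library weights, whose iteration stopped before full convergence, gave 4182, 711 and 3426 for the first, second and last of these, and only the 6 libraries compared gave 198 for CD133+Nestin+ versus CD133+. The block over all libraries took the effect of the number out of the error and moved the median log2 change of all genes by 0. The cause of the other moves was not tested, except that fewer libraries were fitted in the last. Leaving out 1 library gave 1082 to 2763, 131 to 470, 172 to 664 and 862 to 2082 genes, and 16 to 20, 10 to 19 and 8 to 12 lists; where a group keeps 2 libraries they are assumed to vary like the others. The lowest gene counts came without CD133+ replicate 2, CD133+ replicate 3 and Nestin+ replicate 2 (for both CD133+Nestin+ versus Nestin+ and any group), and the lowest list counts without CD133+ replicate 2, CD133+Nestin+ replicate 1 and Nestin+ replicate 3. With an estimated correlation 0 lists passed in each comparison. Lists whose estimate lay under the preset 0.01 also lost their calls, so a larger correlation between genes cannot be the only cause. Among these were the hedgehog list in Nestin+ versus CD133+ (estimate -0.005) and the WNT list in CD133+Nestin+ versus CD133+ (-0.016), each at camera's adjusted p = 0.195. Fry called 14, 10 and 3 lists, the 3 being the ependymal, precursor and tanycyte lists. Other causes were not tested. Of the 178 results for named genes, 0 reversed under any alternative and the block changed 0 calls, while 57 lost their call without CD133+ replicate 3, 55 without Nestin+ replicate 2, 30 with a pseudocount of 0.1 and 29 with only the 6 libraries compared. Apart from Prom1 and Nes these genes were chosen for their calls in the main fit. The lack of reversals was therefore largely fixed by that choice and does not measure stability. Besides the lists given with CD133+Nestin+ versus Nestin+ the block changed the call of 1 more, immediate early genes in CD133+Nestin+ versus CD133+ (adjusted p of 0.0307, and an adjusted p = 0.581 with an estimated correlation). Prom1 and Nes kept their directions without any single library, although the call of Prom1 in CD133+Nestin+ versus Nestin+ was lost without Nestin+ replicate 2 or CD133+Nestin+ replicate 3.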

Other observations

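The tests of a lower share of neural cells, of depth, of a mislabelled sample, of mixed sexes and of the 36 divisions were chosen only after the results they measure were seen. Genes higher in CD133+Nestin+ cells than in both other groups were counted as a further contrast. There were 11, and 0 were lower than in both. Independent lists of the same sizes would share 1.38 and 0.87, and 20 simulations without any effect gave at most 0. The simulations held no difference between any groups and only independent noise, unlike these data, so their 0 is not a test of the overlap. Both comparisons share the CD133+Nestin+ libraries, so the independent expectation is too low and the excess cannot be assigned to biology by these counts. The 11 include the homeobox genes Msx1 (48.3 ± 14.4 CPM, against 12.3 ± 4 in CD133+ and 5.36 ± 1.25 in Nestin+) and Dbx1 (26.7 ± 11.5, against 4.71 ± 0.347 and 6.74 ± 2.22), and the ligand gene Wnt8b (76.4 ± 43.4, against 10.7 ± 4.5 and 14.1 ± 3.8), all n = 3. Anxa1, Npy, Sulf1, Pcolce2, Traf1, Scml4 and Tcerg1l were also among them, with Anxa1 at 149 ± 36.1 CPM and Sulf1 at 301 ± 25.2. All but the rule's named genes were chosen after their values were seen. With the replicate block the 11 passed in both comparisons.

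Most endothelial, microglial and mural list members stood highest in CD133+ libraries, but the mural genes Acta2, Tagln, Prrx1 and Thy1 did not. Library scaling is argued against: all 28 members of the 3 lists that were called lower in Nestin+ cells were also called lower after quantile normalization. For a lower share of neural cells, the ependymal and precursor medians differed by -4.63 (log2) in Nestin+ versus CD133+. Such a share alone would move neural types together, so it cannot be the only difference between the groups. The test cannot decide whether it contributes to the endothelial, microglial and mural lists, because the sort can itself change the mix of neural types. Endothelial, microglial and mural cells within the CD133+ sort may be the source. On 3 further marker lists written before the test, 88.5% of the measured members (23 of 26, of 42 listed) were called lower in Nestin+ cells. In CD133+ against Nestin+ libraries the abundant Lgmn stood at 709 against 196 CPM, Itm2a at 589 against 50.6 and Bgn at 224 against 27.8. Tm4sf1, at 426 CPM in CD133+, stood at 314 in CD133+Nestin+ and 40.6 in Nestin+ cells. Expression of these genes by CD133+ progenitors themselves was not tested and stays open. Whether endothelial, microglial and mural cells also account for the lower interferon, antigen presentation, chemokine and matrix genes was not tested either.

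The libraries numbered 1 stood apart in all 3 groups, with 87.3% to 87.6% of the CPM total in listed genes against 65.9% to 81.0% in the other 6. Sequencing depth is argued against, since all 6 other libraries lay within the range of implied reads of the 3 (1 read at 0.0285 to 0.0344 CPM). More nuclear RNA in the libraries numbered 2 and 3 may contribute: a list of 20 nuclear-retained transcripts, 18 measured, had a median of -1.57 (log2, number 1 minus the others), at percentile 0 of 10000 random lists matched on expression. Malat1, an abundant nuclear transcript outside that list, stood at 894 to 1310 CPM against 3220 to 7680. Genomic length cannot be told apart as a contributor, because its correlation with the difference across genes, -0.15 (Spearman's rho), lay between the bounds set beforehand. The number is also the passage in the labels, so a biological difference between passages stays open and untested.

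CD133+Nestin+ replicate 2 stood apart from its group. A mislabelled single-marker sample is argued against, as 0 of its 2 sort markers lay within the range of a group lacking that marker (Prom1 116 CPM, Nes 172 CPM). More nuclear RNA in that library may contribute: the same nuclear list had a median of 1.42 above the mean of replicates 1 and 3 (percentile 100 of 10000 random lists). The libraries numbered 1 were low on that list as a set, so the median cannot show what is particular to replicate 2. Malat1 stood at 1080, 4550 and 3450 CPM in CD133+Nestin+ replicates 1, 2 and 3. It reached 7680 in Nestin+ replicate 2, which lay at 7.1 on the second principal component. Fewer distinct molecules may also contribute, because the scatter of low genes relative to high genes was 1.78, the highest of the 9 libraries, although CD133+Nestin+ replicate 3 reached 1.73 and its value uses replicate 2 as a reference, so the margin is thin. No biological explanation was tested.

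Xist and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were above the level of 3 reads in 9 of 9 libraries, with Xist at 18.2 to 92.3 CPM and Ddx3y at 12.6 to 57.6, consistent with each library drawn from mice of both sexes.

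In other divisions of the same libraries, 1 of 10 splits gave as many genes as the real one in each pairwise comparison, the real split itself. The real counts were 1915, 390 and 505 and the highest of the other splits 0, 0 and 3 (Nestin+ versus CD133+, CD133+Nestin+ versus CD133+, CD133+Nestin+ versus Nestin+). With 10 splits the share cannot fall under 0.05. Among the 3 other splits of each comparison that also part all 3 same-numbered pairs, the highest count was 0. For the F test, 1 of 100 drawn splits, the real one, reached 1534 genes. The highest other split gave 849, but most of those splits put libraries of the same number into 1 group. Among all 36 divisions in which each group holds every number, run after the drawn splits were seen, 1 reached 1534 genes, the real one, and the highest other gave 484. With the replicate block the values were 2656 and 571, so a chance division of these libraries is excluded at 0.05 for the F test. The labels do not say that the libraries are separate animals or cultures, so this does not extend beyond these samples.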
